A study of Homo sapiens with 24 samples.

How the data were processed

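RNA was measured by sequencing of polyadenylated RNA in 24 libraries of the human embryonic stem cell lines H1 and H9, in 8 groups of 3 that were taken from the sample titles. Per the labels' protocols, RNA was isolated with a column kit and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, reads were aligned with HISAT2 to GRCh38. The aligner's version, the counting tool, the annotation release and the strand setting are not given in the sources used here. The values are whole-number read counts per gene, deposited by the authors in 2 tables without normalization, 1 for the 18 H1 libraries and 1 for the 6 H9 libraries. The table of H1 counts also gives a gene length in bases, deposited by the authors. It holds 27 further columns whose names match no sample described here, and these were not used in any step. Each table lists 60671 genes by Ensembl identifier. Of these, 60401 had a symbol in the gene name table used, and 58453 were found in GENCODE 29 on GRCh38, from which positions and the GC content of each gene's longest transcript were taken.

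From the deposited counts, 6 comparisons were made, namely each of 3 knockdowns against its nontargeting control, naive against primed H9 cells, and, among nontargeting H1 controls, naive against primed cells and day 2 ectoderm against primed cells. Each was fitted with edgeR 4.0.16 in R 4.3.3 on its 2 groups alone. Genes were kept by filterByExpr, libraries were scaled by TMM, and the quasi-likelihood F test (2-sided) was used with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are TMM-scaled CPM of the same fit, so the level of a group differs slightly between fits. A log2 change is the first group minus the control or primed group, and its SE was derived from the F statistic. A fold against a group with no counts used a floor of 3 counts over the group and covers counting error only.

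Gene groups were tested with camera in limma 3.58.1 on the edgeR z scores, with a preset correlation of 0.01, and adjusted over the lists of a comparison. The p with a correlation estimated from the data and the p of fry were computed beside it. The former also rests on the few residual degrees of freedom of a fit, so it can rise without a higher correlation. For the 200 genes highest in naive H9 cells, tested in the CARHSP1 knockdown, the estimated correlation was −0.00205, below the preset. Their unadjusted camera p still went from 1.39e-11 to 0.000334. Fry tests whether a list's genes move, on balance, one way, without comparing them with other genes. The target was left out of its own lists. The 37 lists covered core, naive, primed and 8-cell-like pluripotency, neural ectoderm, the ZIC family, surface ectoderm, neural crest and border, mesendoderm and mesoderm, definitive and primitive endoderm, trophoblast, amnion, fibroblast and germline markers, imprinted genes, DNA methylation and KAP1 and HUSH silencing genes, neighbours of ZNF8 and of CARHSP1, cold shock domain genes, the Nodal and activin list, BMP, WNT, FGF and ERK, NOTCH and p53 targets, Hedgehog genes, the integrated stress and unfolded protein response, immediate early and heat shock, hypoxia and glycolysis, mitochondrially encoded, S phase, mitosis, sterol synthesis and interferon response genes, and cytokine mRNAs with their targets. The marker lists overlap, and genes in several lists are counted in each. Sets of the 200 genes highest in naive and in primed H9 cells were tested in H1, and the 200 genes highest in ectoderm and in primed H1 controls were tested in the ZIC2 knockdown. Because that last pair shares 3 control libraries, the primed, control and knockdown groups were simulated 20 times with the knockdown unchanged from the control. The simulated controls entered both comparisons, and genes were drawn independently. Simulated sets were taken by log2 change alone, without the test, the 5 CPM minimum and the separation of libraries asked of the real sets.

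Genes were named by a rule. It took the 3 targets, the 8 genes up and 8 down with the largest log2 change among those that passed, with a mean of at least 5 CPM and all 3 libraries of a group above all 3 of the other, and up to 4 members of each list with the smallest adjusted p. The text names part of these, and the values of some are not reported here. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. Exceptions are said where they occur.

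Depth lay between 6756704 and 20773963 counts per library. The biological coefficient of variation of the fits was 6.44% for the CARHSP1, 6.57% for the ZNF8 and 9.25% for the ZIC2 comparison, 9.67% for H9, 6.13% for naive against primed H1 and 7.41% for ectoderm. Replicates of a group were compared by a chi-square test over genes with at least 20 counts in a pair. The statistic per degree of freedom ran from 2.44 to 9.16, so no pair looked like repeat copies of a library, and each library was counted as 1 sample. This does not show that the libraries came from separate cultures.

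The tests were checked on simulated data with the real means and library sizes, in which 200 genes and a further planted list were changed. Genes were drawn independently, and far fewer were changed than passed in the real data, so the shares of false calls may not hold there. In the CARHSP1 comparison 71.6% of genes changed 1.5-fold and 98.5% of those changed 4-fold were found, and 3.78% of calls were false. For ZNF8 these values were 59.7%, 97.0% and 5.91%, for ZIC2 59.7%, 98.5% and 4.42%, for H9 52.2%, 93.9% and 7.53%, for naive against primed H1 61.2%, 93.9% and 4.32%, and for ectoderm 59.7%, 97.0% and 5.98%.

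Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a filter of at least 5 CPM, a fit over all groups of the table, the replicate number as a block, an adjusted p threshold of 0.01, a 2-fold minimum, leaving out each library in turn, other set sizes and other set tests. Added after seeing the data was a correction for the 3 knockdowns that removed each library's trends with GC content and gene length by a loess fit with a span of 0.5. Of the genes tested, 99.6% in the CARHSP1 and in the ZIC2 and 99.4% in the ZNF8 comparison had both values. For the difference between H9 and H1, both tables were joined in 1 fit with a line by state term, and each change is taken within its own table.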

Results

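Polyadenylated RNA was sequenced in 24 libraries of human pluripotent stem cells and of cells made from them, in 8 groups of 3. H1 and H9 are established human embryonic stem cell lines. Such cells can be held in a primed state, which resembles the epiblast after implantation, or in a naive state, which resembles the epiblast before it. The 18 H1 libraries comprised a knockdown and a nontargeting control in each of 3 settings, namely CARHSP1 in primed cells, ZNF8 in naive cells and ZIC2 in cells on day 2 of differentiation to ectoderm. The labels list doxycycline for them. The 6 H9 libraries came from primed and naive cells. The labels do not say whether the 3 replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical. Whether the knockdown and control libraries of a pair were handled together is not given in the sources used here.

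Total counts per library ranged from 6756704 to 20773963. The CARHSP1 knockdown libraries held 12849714, 11122564 and 18813356 counts and their primed controls 13175677, 7317419 and 10843152. The ZNF8 knockdown libraries held 20773963, 13824814 and 12249737 counts and their naive controls 12251027, 11853534 and 9679251. The ZIC2 knockdown libraries held 10425879, 12163126 and 9735453 counts and their ectoderm controls 6756704, 10111650 and 12006924. Primed H9 libraries held 15504896, 9429361 and 12569881 counts and naive H9 libraries 11397306, 9130659 and 10633217. Between 20732 and 25392 genes were detected per library. Levels are given in CPM, counts scaled to a common library size, as the mean ± SD of 3 libraries, and changes as log2 ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p. A fold against a group with no counts is a lower bound, taken against 3 counts over the group. Levels of TDGF1, ALPG, KRT8, KRT18, PGK1, LDHA, ENO1, POU5F1, NANOG, the mitochondrial genes and the actin genes ACTA1, ACTC1 and ACTA2 are uncertain. Each has close copies in the genome, and how shared reads were counted is not given in the sources used here. The strand setting of the counting is not given either, so reads of genes that overlap another gene on either strand are uncertain too.

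**Figure D1:**
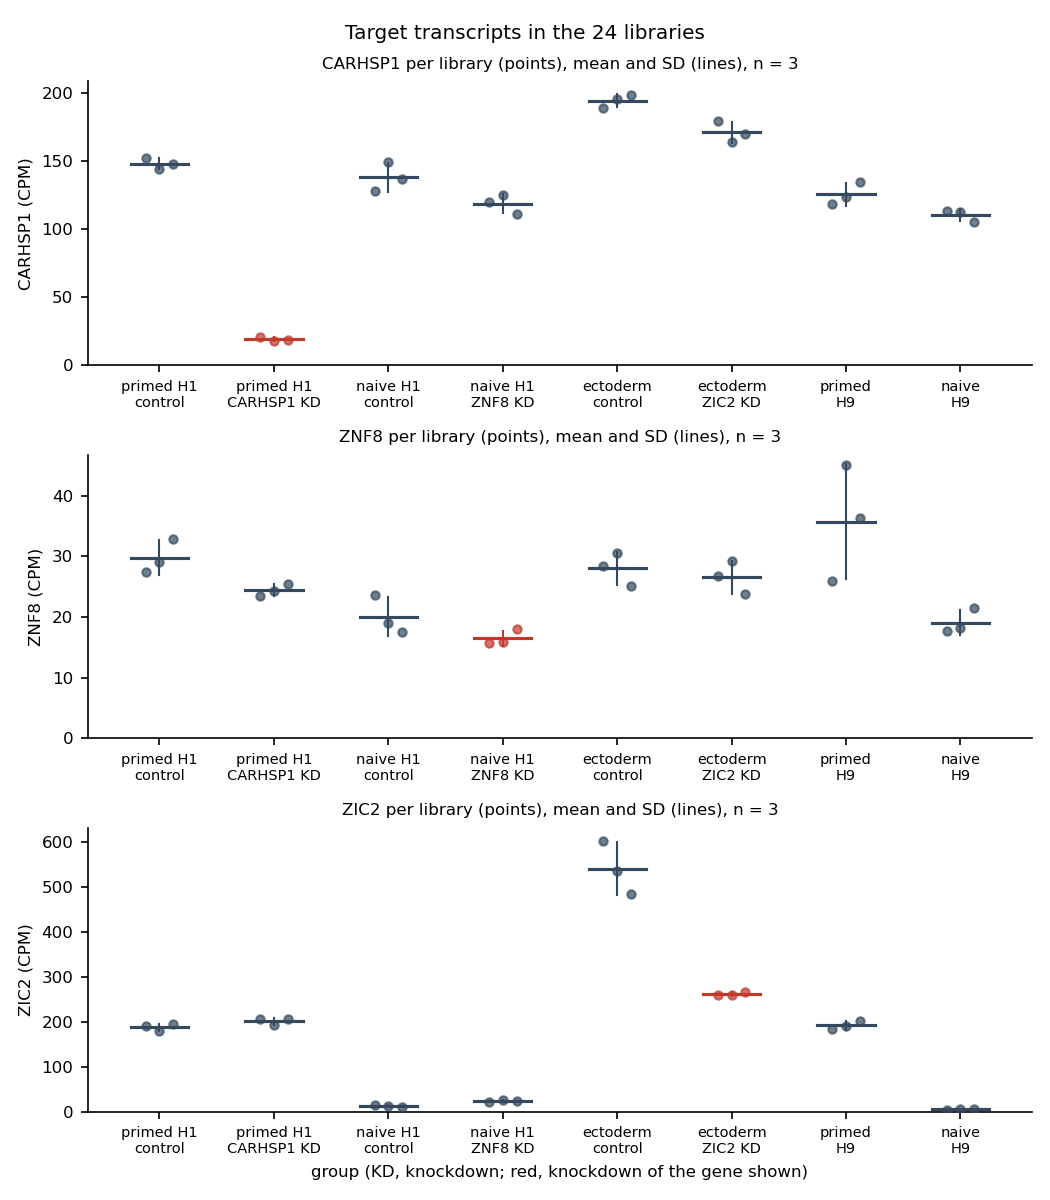
Levels of CARHSP1, ZNF8 and ZIC2 in each of the 24 libraries (y axis, CPM from 0, scaled over all libraries of a table) by group (x axis). Points are libraries, horizontal lines are means and vertical lines are ± 1 SD of 3 libraries, and CARHSP1 and ZIC2 libraries of their own knockdown lie below their controls, while the ZNF8 knockdown libraries, at 15.8 to 18 CPM, overlap their controls at 17.6 to 23.6 CPM.

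Lowering CARHSP1 in primed H1 cells was compared with a nontargeting control to find which transcripts change with this RNA-binding protein of the cold shock domain family. CARHSP1 itself was 7.81-fold lower, at 19.5 ± 1.53 CPM in the knockdown against 152 ± 2.44 in the control (log2 −2.97 ± 0.07; edgeR adjusted p = 8.36e-29), and all 3 knockdown libraries lay below all 3 controls. Transcripts of cholesterol synthesis and of glycolysis and the hypoxia response were lower in the knockdown, transcripts of the p53 response were higher, and TAGLN, MYL9 and ACTC1 were among the genes with the largest increases. The gene, ENSG00000153048, lies on the minus strand of chromosome 16 at 8852942 to 8869012 (GRCh38), where an antisense gene overlapping it was at 1.06 CPM against 1.16. Of the other targets, ZIC2 was at 206 ± 6.78 CPM against 194 ± 5.53 (log2 0.09; edgeR adjusted p = 0.234), a change that reached log2 0.20 and adjusted p = 0.00146 once trends with GC content and gene length were removed. ZNF8 was at 24.9 ± 0.883 against 30.7 ± 2.83 (log2 −0.29 ± 0.10; edgeR adjusted p = 0.0379). That call was lost with DESeq2 (0.0624), with no low-count filter (0.0620), with all groups in one fit (0.0830) and without knockdown replicate 1, 2 or 3 or control replicate 2 or 3 (0.0522 to 0.220).

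In the sterol synthesis list 12 of 15 measured genes were lower at the threshold over all genes and 13 adjusted over the list alone. It fell as a group (camera adjusted p = 7.17e-65, and adjusted p = 0.00226 with an estimated correlation). INSIG1, a sterol sensor of the endoplasmic reticulum, fell from 91.1 ± 5.93 to 35.1 ± 1.29 CPM. MSMO1, a methylsterol oxidase, fell from 183 ± 6.57 to 84.6 ± 6.4. In the hypoxia and glycolysis list 13 of 15 measured genes fell and 1 rose, or 14 and 1 adjusted over the list alone (camera adjusted p = 5.77e-34, and adjusted p = 0.00337 with an estimated correlation). The glucose transporter SLC2A1 fell from 295 ± 5.6 to 154 ± 1.72 CPM and the glycolytic enzyme PGK1 from 836 ± 13.2 to 512 ± 22.1. PFKFB4, which sets the level of a glycolytic activator, fell by 1.91 ± 0.12 on the log2 scale, and BNIP3, a mitochondrial protein induced in low oxygen, from 149 ± 7.5 to 48.8 ± 1.31. SLC16A3, a lactate exporter, showed the largest decrease among the genes picked for size of change apart from CARHSP1, from 30.6 ± 3.26 to 6.95 ± 0.488 CPM (4.40-fold lower; edgeR adjusted p = 8.07e-16).

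Of the 20 measured p53 target genes 16 rose, and 18 did so adjusted over the list alone (camera adjusted p = 1.23e-15, and adjusted p = 0.0465 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 11.4 ± 1.83 to 23.6 ± 2.79 CPM and the antiproliferative gene BTG2 from 4.65 ± 1.56 to 10.8 ± 0.379. The ribonucleotide reductase subunit RRM2B rose from 98.1 ± 6.07 to 141 ± 2.71, and the death receptor TNFRSF10B by log2 0.58. The smooth muscle and actin-binding gene TAGLN rose from 45.1 ± 4.42 to 162 ± 13.2 CPM (3.61-fold; edgeR adjusted p = 5.23e-22) and MYL9, a myosin light chain, from 48.0 ± 1.6 to 144 ± 15.2. The cardiac actin ACTC1 rose from 9.2 ± 0.382 to 23.8 ± 0.525, and ANXA1, a membrane-binding annexin, from 2.07 ± 0.886 to 13.0 ± 0.773. In the naive pluripotency list 9 of 14 measured genes fell, the same number adjusted over the list alone (camera adjusted p = 5.42e-06, but adjusted p = 0.0545 with an estimated correlation). They included GDF3, a TGF-beta ligand, at 14.1 ± 2.23 CPM against 36.9 ± 2.44, the transcription factor TFAP2C with a log2 change of −0.76, and KLF4 at 2.67 against 6.47 CPM. Cytokine mRNAs and their targets, a list chosen because CARHSP1 is known to bind TNF mRNA, had 3 of 5 measured genes lower and 4 adjusted over the list alone (camera adjusted p = 0.0135, but adjusted p = 0.27 with an estimated correlation). Among them was TNFAIP3, an inhibitor of NF-kappaB signalling, at 2.93 ± 0.169 against 8.42 ± 1.12 CPM. NFKBIZ, which is not in that list, was at 6.09 ± 1.73 against 20.3 ± 1.68 CPM.

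The mesendoderm and mesoderm list had 2 of 7 measured genes lower, also adjusted over the list alone (camera adjusted p = 0.000224, but adjusted p = 0.149 with an estimated correlation). One was KDR, a receptor for vascular growth factor, at 136 ± 8.13 CPM against 302 ± 4.89. S phase genes had 6 of 16 higher, also adjusted over the list alone (camera adjusted p = 0.00322, but adjusted p = 0.27 with an estimated correlation), including the thymidylate synthase gene TYMS (log2 0.53). The Hedgehog list had 4 of 10 lower, also adjusted over the list alone (camera adjusted p = 0.0194, but adjusted p = 0.27 with an estimated correlation and 0.173 with GC and length trends removed), led by the receptor gene PTCH1 (log2 −0.49). The fibroblast list was called upward at camera adjusted p = 0.0134 (adjusted p = 0.27 with an estimated correlation), although 2 of its 9 measured genes rose and 2 fell on either adjustment. Mitochondrially encoded genes, 7 of 13 higher and 4 lower on either adjustment, passed at camera adjusted p = 0.0411. This became adjusted p = 0.66 with an estimated correlation, 0.905 with GC and length trends removed, where the direction turned downward, and 0.0629 to 0.183 without knockdown replicate 2 or 3 or control replicate 1 or 2. The core pluripotency list missed the threshold (2 of 16 higher and 5 lower, or 3 and 6 adjusted over the list alone; camera adjusted p = 0.0578). It passed at 0.00395 with GC and length trends removed and at 0.0380 without knockdown replicate 2, with SOX2 at 318 ± 7.55 CPM against 405 ± 8.69. The cold shock domain list of CARHSP1's own relatives (3 of 7 higher, camera adjusted p = 0.427) and the genes next to CARHSP1 (1 of 6 higher, 0.772) did not pass. Nor did the neural crest and border list (1 of 6 higher and 4 lower, 0.0513), WNT targets (3 of 9 lower, 0.0578) and NOTCH targets (5 of 11 lower, 0.102), with the same counts adjusted over each list alone. Without control replicate 2 the neural crest and border list and WNT targets both passed at 0.0348, and without knockdown replicate 3 the former did at 0.0297.

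In all, 3152 of 15642 genes tested passed, 1608 higher and 1544 lower, and 64 of the higher and 176 of the lower ones changed at least 2-fold. All 26 genes named for this pair by rule that passed had the 3 libraries of a group beyond the 3 of the other, as did 36 for ZNF8, 39 for ZIC2, 20 for ectoderm, 17 for H9 and 20 for the states of H1. Chance alone would give this for 10% of genes, but the rule asks it of genes picked by size and passing the test favours it in the rest, so these counts are no test. The count fell to 2045 without control replicate 1 and to 2096 without knockdown replicate 2. Changes followed GC content (Spearman correlation across genes −0.33), and 2016 of the calls were kept among 2603 once trends with GC content and gene length were removed, an alternative chosen after seeing the data.

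**Figure D2:**
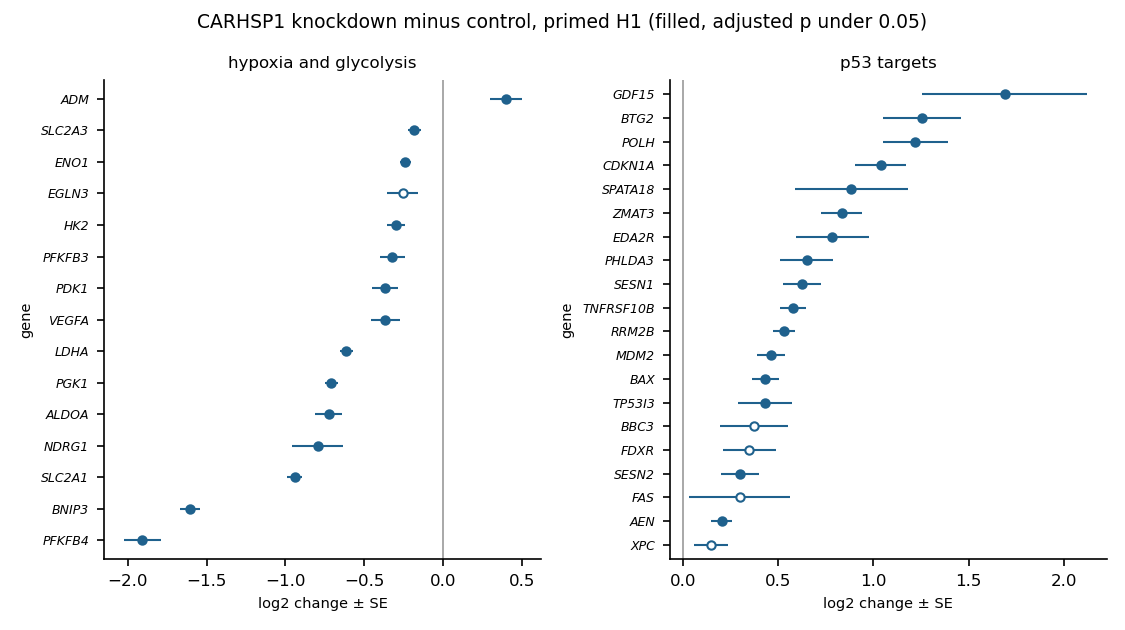
Log2 change (x axis, CARHSP1 knockdown minus nontargeting control in primed H1 cells, points with ± 1 SE, 3 libraries per group) of each measured gene of the hypoxia and glycolysis and the p53 target lists (y axis). Filled points passed the test; 13 of 15 hypoxia and glycolysis genes lie to the left of 0 as filled points, and 16 of 20 p53 targets to the right.

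Lowering ZNF8, a zinc finger protein of the KRAB type, was examined in naive H1 cells. ZNF8 mRNA was at 15.4 ± 1.39 CPM in the knockdown against 19.1 ± 2.85 in the control (log2 −0.32 ± 0.13), which missed the threshold (edgeR adjusted p = 0.0664). The transcript thus gives only weak support to the labels, and the pair is described by them. The change passed with GC and length trends removed (adjusted p = 0.0328) and when replicate 3 of the control or of the knockdown was left out (0.0403 and 0.0413). Between these libraries, genes of trophoblast, amnion and surface ectoderm and genes of the naive state were lower in the knockdown, while the fibroblast list, the list of the integrated stress and unfolded protein response and the sterol synthesis list were higher. ZNF8, ENSG00000278129, lies on the plus strand of chromosome 19 at 58278951 to 58302805 (GRCh38) and shares its locus with a readthrough transcript counted at 0.308 against 0.471 CPM. Of the other targets, ZIC2 was higher, at 22.0 ± 2.23 CPM against 12.5 ± 1.35 (log2 0.80 ± 0.13; edgeR adjusted p = 8.78e-06). CARHSP1 was lower, at 110 ± 5.51 against 131 ± 9.99 (edgeR adjusted p = 0.00281, or 0.0574 without control replicate 2).

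GATA3, a transcription factor of trophoblast and amnion, was 51.4-fold lower, at 0.313 ± 0.0659 CPM against 16 ± 1.08 (log2 −5.68 ± 0.28; edgeR adjusted p = 2.98e-19). In the trophoblast list 8 of 10 measured genes fell (camera adjusted p = 8.39e-15, and adjusted p = 0.0344 with an estimated correlation). In the surface ectoderm list 11 of 13 fell and 1 rose (camera adjusted p = 6.74e-17, and adjusted p = 0.035 with an estimated correlation). In the amnion list 4 of 8 fell and 1 rose (camera adjusted p = 1.35e-05, and adjusted p = 0.035 with an estimated correlation). Adjusted over the list alone, these counts were the same. GATA2 (log2 −0.22; edgeR adjusted p = 0.339) and ENPEP (log2 −0.09; 0.859) of the trophoblast list and GADD45G (log2 −0.02; 0.951) of the amnion list did not pass. IGFBP3 of the amnion list rose by log2 0.82 and GRHL3 of the surface ectoderm list by log2 0.71, and of these 5 genes all but IGFBP3 were chosen after their values were seen. HAND1, a factor of trophoblast and amnion, fell from 6.21 to 0.466 CPM, the homeobox gene DLX5 by 3.10 on the log2 scale and TFAP2A, a factor of surface ectoderm and trophoblast, from 27.7 ± 0.685 to 8.74 ± 0.916 CPM. The immune checkpoint ligand gene VTCN1 fell by 4.23 on the log2 scale and GABRP, a GABA receptor subunit found in amnion, by 3.46. The hypoxia-inducible factor gene EPAS1 was at 1.60 ± 0.817 CPM against 17.3 ± 2.16, the protogenin gene PRTG at 1.29 ± 0.508 against 60.2 ± 8.78, and PKDCC, a secreted kinase, at 2.31 ± 0.775 against 77.8 ± 4.69.

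Of the 18 measured genes of the naive list 13 fell, also adjusted over the list alone (camera adjusted p = 3.81e-28, and adjusted p = 0.0123 with an estimated correlation). KLF17, a factor specific to the naive state, fell 7.0-fold, from 10.3 ± 1.07 to 1.42 ± 0.306 CPM (edgeR adjusted p = 5.38e-12), and NLRP7 from 237 ± 4.5 to 66.4 ± 0.71. The placental-type phosphatase ALPG fell from 71.8 ± 1.44 to 17.6 ± 1.24 and DNMT3L, a cofactor of de novo DNA methylation, from 51.1 ± 4.46 to 15.3 ± 0.604. The core pluripotency list had 6 of 16 genes lower, also adjusted over the list alone (camera adjusted p = 0.0011, but adjusted p = 0.233 with an estimated correlation), LIN28A among them (log2 −0.37). DNA methylation genes had 5 of 11 lower, also adjusted over the list alone (camera adjusted p = 0.000729, but adjusted p = 0.0659 with an estimated correlation). They included DNMT3B at 712 ± 19 CPM against 991 ± 13.8 and the demethylase TET2 (log2 −0.69). The primed list had 4 of 17 higher and 6 lower on either adjustment and did not pass (camera adjusted p = 0.068, and downward at 0.0429 with GC and length trends removed and 0.0431 without control replicate 3).

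Among groups that rose, the fibroblast list had 6 of 7 genes higher, also adjusted over the list alone (camera adjusted p = 8.54e-10, and adjusted p = 0.035 with an estimated correlation). The collagen gene COL1A2 was at 375 ± 13.5 CPM against 285 ± 6.25, and the smooth muscle actin ACTA2 was up by log2 2.66. TAGLN rose from 18.6 ± 0.314 to 89.6 ± 5.31 CPM (4.79-fold; edgeR adjusted p = 6.98e-23), ACTC1 from 4.18 ± 0.0256 to 25.7 ± 3.45 and MYL9 from 60.5 ± 5.14 to 209 ± 14.8. In the list of the integrated stress and unfolded protein response 6 of 14 rose and 1 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 4.39e-07, and adjusted p = 0.0344 with an estimated correlation). The serine synthesis genes PHGDH and PSAT1 rose from 108 ± 2.02 to 217 ± 3.69 and from 111 ± 1.33 to 238 ± 13.2 CPM. The mitochondrial PCK2 rose from 10.1 ± 1.32 to 47.1 ± 0.409 and the arginine transporter SLC7A1 from 19.4 ± 2.05 to 73.4 ± 2.54. Sterol synthesis had 12 of 15 higher and 1 lower, or 13 and 1 adjusted over the list alone (camera adjusted p = 6.74e-17, and adjusted p = 0.0123 with an estimated correlation). HMGCS1 was at 569 ± 24.2 CPM against 375 ± 6.81. Mitochondrially encoded genes had 9 of 13 higher and 11 adjusted over the list alone (camera adjusted p = 1.27e-10, but adjusted p = 0.244 with an estimated correlation).

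The hypoxia and glycolysis list had 10 of 16 lower and 1 higher, or 11 and 1 adjusted over the list alone (camera adjusted p = 1.15e-14, and adjusted p = 0.0123 with an estimated correlation). The lactate dehydrogenase LDHA was at 309 ± 10.6 CPM against 818 ± 9.35 (log2 −1.41 ± 0.05; edgeR adjusted p = 1.03e-24) and BNIP3 at 106 against 191. S phase genes had 10 of 16 lower and 13 adjusted over the list alone (camera adjusted p = 9.01e-06, and adjusted p = 0.035 with an estimated correlation), with the replication clamp PCNA at log2 −0.40. BMP targets had 5 of 9 lower and 1 higher on either adjustment (camera adjusted p = 0.000372, but adjusted p = 0.233 with an estimated correlation), ID4 and MSX2 falling by 1.95 and 1.98 on the log2 scale. KRAB zinc finger proteins act through the KAP1 and HUSH silencing complexes, whose list had 5 of 13 lower and 1 higher, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0307, but adjusted p = 0.233 with an estimated correlation and 0.0685 without control replicate 1). The histone deacetylase HDAC1 was at log2 −0.30. Genes next to ZNF8, 1 of 19 higher and 2 lower, did not pass (camera adjusted p = 0.994). Nor did the imprinted list (3 of 12 higher and 1 lower, 0.981), the germline list (1 of 5 higher and 2 lower, 0.715) or the Nodal and activin list (4 of 11 higher and 3 lower, 0.771), with the same counts adjusted over each list alone. The 8-cell-like list had 2 measured genes, of which 1 rose, also adjusted over the list alone, too few for a set test.

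In all, 3702 of 15323 genes passed, 1824 higher and 1878 lower, with 217 of the higher and 362 of the lower ones at least 2-fold changed.

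**Figure D3:**
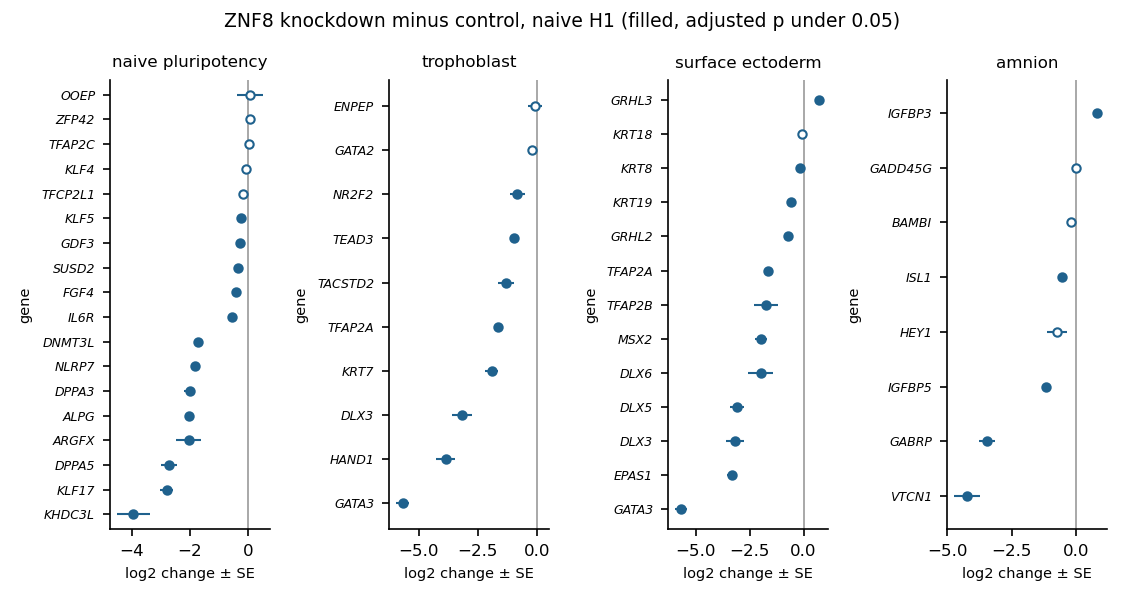
Log2 change (x axis, ZNF8 knockdown minus nontargeting control in naive H1 cells, points with ± 1 SE, 3 libraries per group) of each measured gene of the naive pluripotency, trophoblast, surface ectoderm and amnion lists (y axis). Filled points passed the test; 13 of 18 naive genes, 8 of 10 trophoblast genes, 11 of 13 surface ectoderm genes and 4 of 8 amnion genes lie below 0 as filled points.

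Lowering ZIC2, a zinc finger transcription factor of the early neural plate, was examined on day 2 of ectoderm differentiation. ZIC2 was 2.08-fold lower, at 272 ± 4.67 CPM against 566 ± 63.1 (log2 −1.06 ± 0.07; edgeR adjusted p = 1.18e-10), with all 3 knockdown libraries below all 3 controls. Of the 200 genes highest in day 2 ectoderm, a set chosen with the same control libraries, 121 were lower in the knockdown. The lists of p53 targets, of the integrated stress and unfolded protein response, of FGF and ERK targets and of surface ectoderm were higher. In the neural ectoderm list 10 of 18 genes fell and 4 rose, and its downward call was lost with an estimated correlation (adjusted p = 0.134). The gene, ENSG00000043355, lies on the plus strand of chromosome 13 at 99981772 to 99986773 (GRCh38). CARHSP1 was at 177 ± 8.98 CPM against 203 ± 4.44 (edgeR adjusted p = 0.0215), a call lost without replicate 2 or 3 of the knockdown or of the control (adjusted p from 0.0524 to 0.127). ZNF8 did not pass (log2 −0.09; edgeR adjusted p = 0.654).

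NPTX1, a pentraxin of neural cells, was 14.9-fold lower, at 11.7 ± 0.6 CPM against 175 ± 13.1 (edgeR adjusted p = 3.67e-18), and the dopamine receptor DRD2 was at 0.805 against 9.23 CPM. FLRT3, a cell adhesion protein, was at 7.96 ± 0.629 against 48.8 ± 1.6, and SEZ6, a neuronal membrane protein, at 52.3 ± 1.6 against 225 ± 17.2. Of the 18 measured neural ectoderm genes 10 fell and 4 rose, or 10 and 5 adjusted over the list alone. The set test was downward (camera adjusted p = 4.72e-07, but adjusted p = 0.134 with an estimated correlation), as was the median log2 change of −0.59. The mean was 0.03, or −0.14 with the 1 gene that had no counts in a group at its lower bound. HESX1, a homeobox gene of the anterior neural plate, fell from 83.1 ± 6.01 to 34.5 ± 3 CPM, and POU3F1, a neural POU factor, from 75.4 ± 11.3 to 32.3 ± 1.3. OTX2, a forebrain factor, fell from 572 ± 50.6 to 355 ± 10.4, and N-cadherin, CDH2, from 169 to 92.6. Among ZIC2's relatives ZIC1 fell from 296 ± 20.7 to 185 ± 16 CPM and ZIC4 by 1.45 on the log2 scale. The ZIC family list did not pass (1 of 4 higher and 2 lower on either adjustment, camera adjusted p = 0.182).

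In the p53 target list 19 of 20 measured genes rose, also adjusted over the list alone (camera adjusted p = 4e-30, and adjusted p = 0.0264 with an estimated correlation). CDKN1A rose 6.56-fold, from 9.73 ± 1.42 to 63.6 ± 4.16 CPM (log2 2.71 ± 0.13; edgeR adjusted p = 5.45e-13), BTG2 from 4.56 to 25 and MDM2, the ubiquitin ligase that degrades p53, from 49.2 to 106. In the list of the integrated stress and unfolded protein response 13 of 15 rose and 1 fell on either adjustment (camera adjusted p = 2.34e-17, and adjusted p = 0.0256 with an estimated correlation). PSAT1 was at 812 ± 11.2 CPM against 323 ± 13.1, the cystine transporter SLC7A11 at 123 ± 12 against 29.9 ± 4.64, and the stress sensor SESN2, also a p53 target, was up by log2 1.35. FGF and ERK targets had 9 of 14 higher, also adjusted over the list alone (camera adjusted p = 1.64e-16, and adjusted p = 0.0264 with an estimated correlation). They included SPRY4, a feedback inhibitor of the pathway, at 63.1 ± 4.31 CPM against 10.4 ± 1.66, ETV5 at 29.5 against 4.25 and ETV4 (log2 1.24).

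TDGF1, a co-receptor for Nodal and a marker of pluripotent cells, was 29.9-fold higher, at 197 ± 16.7 CPM against 6.65 ± 1.16 (log2 4.90 ± 0.11; edgeR adjusted p = 2.76e-18). SPP1, osteopontin, was at 123 ± 10 against 9.11 ± 2.4. The Nodal and activin list, which holds TDGF1, had 3 of 7 higher, also adjusted over the list alone (camera adjusted p = 9.73e-08, and adjusted p = 0.0264 with an estimated correlation). FOXH1 rose by log2 0.76, or by 0.41 with GC and length trends removed. Surface ectoderm genes had 6 of 8 higher, also adjusted over the list alone (camera adjusted p = 1.62e-09, and adjusted p = 0.0264 with an estimated correlation). The keratins KRT8 and KRT18 were at 302 ± 17.8 against 138 ± 15.3 CPM and 174 ± 1.38 against 75.6 ± 2.21, and the epidermal factor GRHL3 was up by log2 3.68. The fibroblast list had 3 of 8 higher and 5 adjusted over the list alone (camera adjusted p = 1.26e-07, and adjusted p = 0.0264 with an estimated correlation). TAGLN rose 9.31-fold, from 12 ± 0.738 to 113 ± 6.35 CPM, ANXA1 from 0.0825 ± 0.0753 to 21.6 ± 0.451, and the skeletal actin ACTA1 from 0.0283 ± 0.049 to 11.3 ± 4.44. The AP-1 subunit FOSL1 rose from 2.57 ± 0.756 to 25.9 ± 1.27 and the vasoconstrictor gene EDN1 from 2.32 ± 0.802 to 31.5 ± 2.5. GATA3, with no counts in the 3 controls, reached 2.20 ± 0.656 CPM, at least 21.2-fold higher.

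Further lists passed in camera only with the preset correlation. Fry, which does not compare a list with other genes, called 23 of the 36 lists tested in this knockdown. Core pluripotency had 5 of 15 higher and 4 lower on either adjustment (called upward, camera adjusted p = 0.0158, but adjusted p = 0.152 with an estimated correlation). Its median log2 was −0.03 and its mean 0.46, and SOX2 was lower (log2 −0.50). Primitive endoderm, 3 of 8 higher and 3 lower on either adjustment, was called downward (camera adjusted p = 0.0268, but adjusted p = 0.188 with an estimated correlation, 0.0695 with all groups in one fit and 0.0616 without control replicate 3). Its median was 0.09 and its mean −0.35. Amnion had 3 of 4 higher and 1 lower on either adjustment (camera adjusted p = 0.0398, but adjusted p = 0.374 with an estimated correlation, 0.284 with a stricter filter, 0.0705 without knockdown replicate 1 and 0.0636 without control replicate 3). The KAP1 and HUSH list had 8 of 13 lower and 1 higher, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.0258, but adjusted p = 0.334 with an estimated correlation and 0.0705 without knockdown replicate 1). TRIM28, which encodes KAP1, rose (log2 0.56, but 0.18 with GC and length trends removed). Mitosis genes had 6 of 14 lower and 1 higher, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0164, but adjusted p = 0.152 with an estimated correlation and 0.0583 with GC and length trends removed). The topoisomerase TOP2A was at log2 −0.45. The hypoxia and glycolysis list went both ways, 6 of 15 higher and 5 lower on either adjustment (camera adjusted p = 0.987), VEGFA rising by log2 1.61 and PGK1 falling by 1.02 on the log2 scale. The interferon response list (6 of 8 higher, camera adjusted p = 0.0946) did not pass, with the same count adjusted over the list alone.

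In all, 4217 of 15013 genes passed, 2292 higher and 1925 lower, with 570 of the higher and 229 of the lower ones at least 2-fold changed. Changes followed GC content (Spearman correlation across genes 0.33), and 2863 of the calls were kept among 3550 with GC and length trends removed, an alternative chosen after seeing the data.

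Among the nontargeting controls, ectoderm on day 2 was compared with primed H1 cells to see what changed with differentiation. SIX3, a forebrain homeobox factor, rose from 0.0763 to 195 ± 18.4 CPM (log2 10.82 ± 0.20). LHX5, a LIM homeobox gene of the forebrain, rose from 0.188 to 112 ± 3.98 and OTX2 from 32.4 ± 4.5 to 570 ± 51.4. TDGF1 fell from 917 ± 30.8 to 6.63 ± 1.15 (log2 −7.13 ± 0.09; edgeR adjusted p = 3.9e-31) and NANOG from 135 ± 1.84 to 3.98 ± 0.291. ZEB2, a repressor in neural cells, went from no counts to 130 ± 8.65 CPM, at least 1356-fold higher. Of 17 measured neural ectoderm genes 15 rose and 1 fell, or 16 and 1 adjusted over the list alone (camera adjusted p = 1.24e-37, and adjusted p = 0.0206 with an estimated correlation). The early neural gene SOX1 was at 12.1 ± 1.97 against 0.0613 CPM. All 5 measured ZIC family genes rose, also adjusted over the list alone (camera adjusted p = 6.29e-15, and adjusted p = 0.0206 with an estimated correlation). ZIC1 rose from 6.84 ± 1.77 to 295 ± 20.9 CPM and ZIC2 from 194 ± 6.01 to 564 ± 63.6 (edgeR adjusted p = 2.86e-18). CARHSP1 was higher too, at 203 against 153 CPM (edgeR adjusted p = 5.82e-07), and ZNF8 did not pass (log2 −0.08; edgeR adjusted p = 0.576).

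Core pluripotency genes mostly fell, 12 of 16 with 4 higher on either adjustment (camera adjusted p = 3.17e-12, and adjusted p = 0.0206 with an estimated correlation). POU5F1 went from 1435 ± 76.2 to 451 ± 53.2 CPM, while LIN28A rose (log2 1.07). All 10 measured Nodal and activin genes fell, also adjusted over the list alone (camera adjusted p = 9.53e-24, and adjusted p = 0.0385 with an estimated correlation), among them SKIL (log2 −3.58) and SMAD7 (log2 −3.27), both feedback inhibitors. Sterol synthesis had 13 of 15 lower (camera adjusted p = 5.25e-08, and adjusted p = 0.0321 with an estimated correlation). Hypoxia and glycolysis had 12 of 15 lower and 1 higher (camera adjusted p = 2.89e-07, and adjusted p = 0.0321 with an estimated correlation), with the same counts adjusted over each list alone. SLC2A1 went from 296 to 79.6 CPM. All 13 mitochondrially encoded genes fell, also adjusted over the list alone (camera adjusted p = 3.2e-27, but adjusted p = 0.0653 with an estimated correlation). These genes took 1.79% to 2.18% of counts in the ectoderm control libraries against 5.46% to 5.73% in the primed ones. FGF and ERK targets had 12 of 14 lower and 2 higher on either adjustment (camera adjusted p = 1.2e-12, but adjusted p = 0.0584 with an estimated correlation). DUSP6, a phosphatase that limits ERK, fell by 6.03 on the log2 scale.

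Mitosis genes had 10 of 14 higher and 1 lower on either adjustment (camera adjusted p = 0.000108, but adjusted p = 0.0584 with an estimated correlation), with the checkpoint kinase BUB1 at 726 ± 39.7 CPM against 208 ± 2.77. Naive genes had 11 of 15 lower and 1 higher (camera adjusted p = 0.00086, but adjusted p = 0.0658 with an estimated correlation). Surface ectoderm genes had 6 of 7 lower (camera adjusted p = 1.17e-05, but adjusted p = 0.0812 with an estimated correlation). BMP targets had 7 of 9 lower and 1 higher (camera adjusted p = 1.56e-05, but adjusted p = 0.103 with an estimated correlation). The counts of these 3 lists were the same adjusted over the list alone. The BMP response gene ID1 went from 50.7 to 0.78 CPM and KRT18 fell by 2.14 on the log2 scale. Mesendoderm genes had 5 of 7 lower and 6 adjusted over the list alone (camera adjusted p = 0.00368, but adjusted p = 0.146 with an estimated correlation). Fibroblast genes had 7 of 9 lower and 2 higher on either adjustment (camera adjusted p = 0.00633, but adjusted p = 0.103 with an estimated correlation). Immediate early and heat shock genes had 6 of 12 lower and 1 higher on either adjustment (camera adjusted p = 0.00782, but adjusted p = 0.249 with an estimated correlation), FOS falling by 4.31 on the log2 scale. Primitive endoderm genes had 5 of 9 higher and 4 lower on either adjustment (called upward, camera adjusted p = 0.00055, but adjusted p = 0.157 with an estimated correlation). In all, 9680 of 15409 genes passed, 4727 higher and 4953 lower. All of these differences are bound up with the change of culture between the states.

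Genes that separate day 2 ectoderm from primed cells moved the other way in the ZIC2 knockdown. Of the 200 genes highest in ectoderm over primed cells, 121 fell and 11 rose in the knockdown (camera adjusted p = 7.42e-41, and adjusted p = 0.000903 with an estimated correlation). Their median log2 was −0.51, against −0.014 on average in 20 simulations of an unchanged knockdown. There, simulated controls entered both comparisons and sets were picked by log2 change alone. Of the 200 highest in primed cells, 185 were measured and 121 rose while 1 fell (median log2 1.19, against 0.064 in the simulations; camera adjusted p = 3.46e-38, and adjusted p = 0.00149 with an estimated correlation). Over 14748 genes the changes of both comparisons had a correlation across genes of −0.60, against −0.10 on average in the simulations, and a covariance of −0.352 against −0.0260, a difference of −0.326. Both comparisons use the same 3 ectoderm controls, which are too few to split into groups of 2, so part of the excess may come from them.

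**Figure D4:**
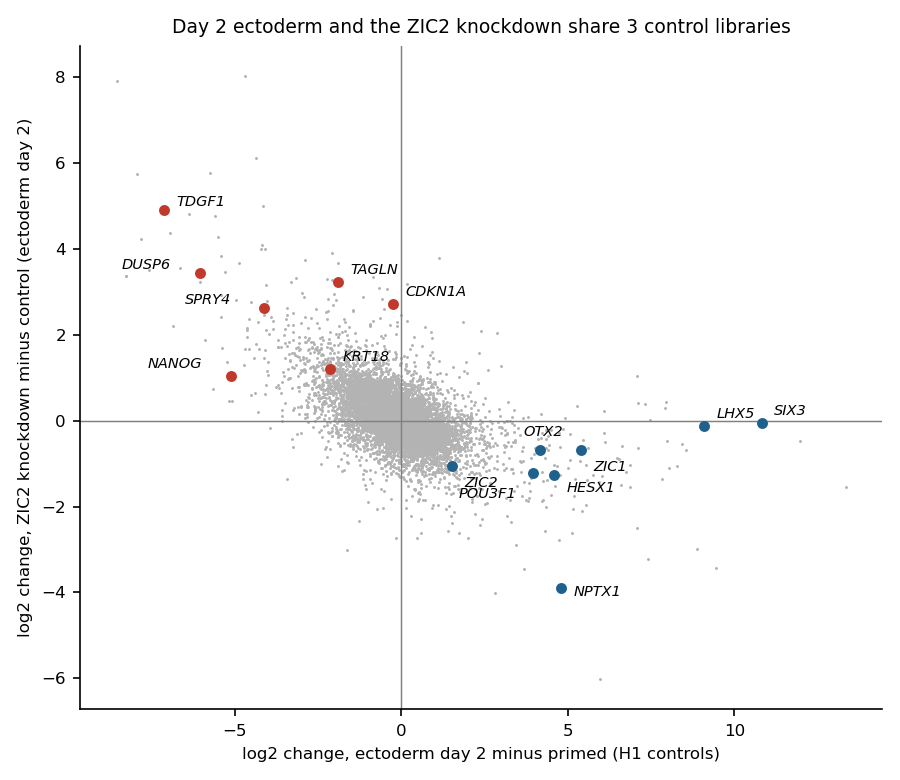
Log2 change of ectoderm day 2 minus primed cells among nontargeting H1 controls (x axis) against log2 change of ZIC2 knockdown minus control on day 2 (y axis) for 14748 genes tested in both (grey points), with named genes in red where higher and in blue where lower in the knockdown, whether or not they passed. TDGF1 lies at −7.13 and 4.90 and OTX2 at 4.16 and −0.69, and the cloud slopes downward, in part because both axes share the same 3 control libraries.

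Naive and primed cells were compared in H9 and, with nontargeting controls, in H1. In both lines naive cells had more NLRP7, a maternal-effect gene of the naive state, and more FGF4, a growth factor of early epiblast, and less ZIC2 and THY1, a surface marker of primed cells. In H9, NLRP7 was at 156 ± 1.89 CPM in naive cells against 2.44 ± 0.174 in primed cells (log2 6.0 ± 0.13) and FGF4 at 170 ± 1.74 against 2.36 ± 0.331. ZIC2 was at 5.46 ± 0.574 against 192 ± 7.85 (log2 −5.14 ± 0.12; edgeR adjusted p = 5.37e-17) and THY1 at 27.9 ± 0.151 against 145 ± 16.2. ZNF8 was lower in naive H9 cells, at 19.2 ± 2.11 against 35.8 ± 9.76 CPM (edgeR adjusted p = 0.000172), and CARHSP1 did not pass (log2 −0.18; edgeR adjusted p = 0.0948). The naive list had 17 of 18 measured genes higher and 1 lower (camera adjusted p = 5.09e-34, and adjusted p = 0.0212 with an estimated correlation). The primed list had 19 of 21 lower and 1 higher (camera adjusted p = 2.45e-32, and adjusted p = 0.0212 with an estimated correlation). The ZIC family had 2 of 3 lower and 1 higher (camera adjusted p = 1.16e-12, and adjusted p = 0.0212 with an estimated correlation). These counts held on either adjustment. DNMT3L was at 12.9 ± 1.95 against 0.318 CPM, and OTX2 at 25.1 ± 1.23 against 125 ± 6.93.

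Sterol synthesis had 13 of 15 genes higher in naive H9 cells (camera adjusted p = 5.59e-09, and adjusted p = 0.0254 with an estimated correlation). Nodal and activin genes had 8 of 11 higher and 1 lower (camera adjusted p = 8.32e-16, but adjusted p = 0.0922 with an estimated correlation). The Nodal inhibitor LEFTY2 was at 263 ± 17.6 CPM against 2.93 ± 0.533 and NODAL at 31.4 against 0.681. FGF and ERK targets had 8 of 14 lower and 4 higher (camera adjusted p = 3.69e-05, but adjusted p = 0.0922 with an estimated correlation). The immediate early factor EGR1 was at 1.84 ± 0.101 against 176 ± 11 and DUSP6 at 0.169 ± 0.0697 against 18 ± 3.2. Fibroblast genes had 6 of 7 lower and 1 higher (camera adjusted p = 5.18e-09, but adjusted p = 0.0922 with an estimated correlation), COL1A1 falling by 2.23 on the log2 scale. Neural ectoderm genes had 8 of 14 lower and 3 higher (camera adjusted p = 0.000415, but adjusted p = 0.111 with an estimated correlation), although the eye field factor PAX6 rose to 9.08 from 0.0258 CPM. Each of these counts was the same adjusted over the list alone. Among the genes with the largest increases in H9 were the zinc finger genes ZNF229, ZNF560 and ZNF528, ZNF229 reaching 12.9 ± 1.7 CPM from no counts (at least 161-fold), ZNF560 28.9 ± 3.52 from 0.0258 and ZNF528 25.7 from 0.0606.

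Further H9 lists passed in camera only with the preset correlation. Fry, which does not compare a list with other genes, called 30 of the 36 lists tested in H9. Hypoxia and glycolysis had 9 of 17 higher and 2 lower (camera adjusted p = 0.00226, but adjusted p = 0.0947 with an estimated correlation). Mitochondrially encoded genes had 12 of 13 higher (camera adjusted p = 0.00326, but adjusted p = 0.468 with an estimated correlation). Definitive endoderm had 4 of 5 higher (camera adjusted p = 0.0146, but adjusted p = 0.202 with an estimated correlation), led by CER1, a secreted Nodal and BMP inhibitor (log2 5.32). BMP targets had 4 of 10 higher and 1 lower (camera adjusted p = 0.0281, but adjusted p = 0.18 with an estimated correlation and 0.0950 with a stricter filter), with the same counts adjusted over each of these lists alone. Immediate early and heat shock genes had 6 of 12 lower and 3 higher, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.0146, but adjusted p = 0.149 with an estimated correlation). In all, 8119 of 15761 genes passed in H9, 4009 higher and 4110 lower in naive cells.

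In H1, naive cells expressed KLF17 at 10.7 ± 1.11 CPM against no counts in primed cells, at least 112-fold higher, and WNT8A, a secreted WNT ligand, at 23.5 against none, at least 245-fold higher. KLF17 was nearly absent from naive H9 cells, at 0.0687 CPM in the joint fit of both tables against 10.8 in naive H1 cells. LEFTY2 was at 1726 ± 14.6 CPM against 11.1 ± 0.465 (log2 7.29 ± 0.06; edgeR adjusted p = 3.95e-72). KLF5 was at 189 ± 7.16 against 8.1 ± 2.51, the surface protein SUSD2 at 117 ± 2.2 against 6.05 ± 0.882 and DNMT3L at 53 ± 4.66 against 0.139. NLRP7 was at 246 ± 4.53 against 4.42 CPM and FGF4 at 482 ± 6.77 against 13.8 ± 1.4. ZIC2 was at 13.0 ± 1.4 against 189 ± 6.13 (log2 −3.86 ± 0.08; edgeR adjusted p = 6.67e-49) and THY1 at 0.499 ± 0.253 against 409 ± 2.58. SFRP2, a secreted WNT modulator, was at 0.376 ± 0.286 against 409 ± 13.1 and the receptor phosphatase PTPRZ1 at 3.19 against 431 ± 22.3. ZNF8 was lower by log2 −0.59 ± 0.12 (edgeR adjusted p = 1.33e-05). CARHSP1 passed narrowly (log2 −0.13; edgeR adjusted p = 0.0301) but not with DESeq2 (0.0686) or without naive replicate 1 or primed replicate 1, 2 or 3 (0.0541 to 0.267).

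No list of the H1 state comparison passed with an estimated correlation, a test that also has few residual degrees of freedom. Fry called 31 of the 36 lists tested. The primed list had 18 of 21 lower and 2 higher (camera adjusted p = 1.96e-35, but adjusted p = 0.0833 with an estimated correlation). The naive list had 17 of 18 higher and 1 lower (camera adjusted p = 1.19e-24, but adjusted p = 0.0833 with an estimated correlation). All 11 Nodal and activin genes rose (camera adjusted p = 2.29e-20, but adjusted p = 0.0833 with an estimated correlation). Of the 14 FGF and ERK targets 13 fell (camera adjusted p = 3.86e-17, but adjusted p = 0.0833 with an estimated correlation), SPRY4 from 172 ± 4.02 to 0.0918 CPM. Surface ectoderm genes had 11 of 12 higher and 1 lower (camera adjusted p = 2.27e-05, but adjusted p = 0.153 with an estimated correlation). TFAP2A was at 28.7 against 0.159 CPM and KRT8 at 1632 against 441. Amnion genes had 5 of 8 higher and 2 lower (camera adjusted p = 0.00276, but adjusted p = 0.221 with an estimated correlation). GATA3 was at 16.6 against 0.603 CPM, and HAND1 was at least 67.3-fold higher in naive cells, with no counts in primed ones. Mitosis genes had 13 of 14 lower (camera adjusted p = 7.95e-08, but adjusted p = 0.153 with an estimated correlation), TOP2A at 213 ± 10.3 against 699 ± 13.4 CPM. ZIC genes had 3 of 4 lower (camera adjusted p = 2.27e-05, but adjusted p = 0.153 with an estimated correlation). Fibroblast genes had 6 of 8 lower and 1 higher (camera adjusted p = 0.00364, but adjusted p = 0.153 with an estimated correlation).

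Definitive endoderm (3 of 6 higher and 2 lower, camera adjusted p = 0.0424) and mesendoderm (5 of 9 higher and 2 lower, 0.043) passed in H1 with an adjusted p = 0.432 with an estimated correlation for both. Both were lost without naive replicate 3 (0.228 and 0.0624) or primed replicate 1 (0.0585 and 0.056), mesendoderm also without primed replicate 3 (0.0616). The trophoblast list did not pass in H1 (8 of 11 higher and 2 lower, camera adjusted p = 0.114). Counts were the same adjusted over each list alone. In all, 11289 of 15874 genes passed in H1, 5557 higher and 5732 lower in naive cells. State is confounded with culture medium and handling in both lines.

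Genes that separate the states in H9 did so in H1 as well. Of the 200 genes highest in naive over primed H9 cells, 198 were measured in H1 and 153 were higher and 25 lower in naive cells (median log2 1.42; camera adjusted p = 5.67e-29, and adjusted p = 0.0116 with an estimated correlation). Of the 200 highest in primed H9 cells 166 of 197 were lower and 12 higher (median log2 −2.39; camera adjusted p = 9.73e-34, and adjusted p = 0.0116 with an estimated correlation). In the CARHSP1 knockdown the naive set had 65 of 189 genes lower and 10 higher (median log2 −0.28; camera adjusted p = 3.72e-11, and adjusted p = 0.00267 with an estimated correlation). In the ZNF8 knockdown it had 64 of 195 lower and 35 higher (median −0.13; camera adjusted p = 0.000136, and adjusted p = 0.0116 with an estimated correlation). In the ZIC2 knockdown it had 46 of 165 higher and 14 lower (median 0.22; camera adjusted p = 6.62e-05, and adjusted p = 0.0166 with an estimated correlation). With the top 50 genes in place of 200, these 3 calls of the naive set were lost with an estimated correlation (adjusted p = 0.101 for each). The primed set did not pass in the CARHSP1 knockdown (32 of 198 higher and 29 lower, camera adjusted p = 0.849) or the ZNF8 knockdown (38 of 157 higher and 33 lower, camera adjusted p = 0.724, with the test and the mean of −0.16 downward and the median of 0.03 upward). In the ZIC2 knockdown 57 of 194 were higher and 36 lower (median 0.10; camera adjusted p = 0.0288, but adjusted p = 0.176 with an estimated correlation and 0.0979 and 0.289 for the top 50 and 500). Putting the 2 and 3 genes with no counts in a group at their bound left the medians in H1 as given.

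**Figure D5:**
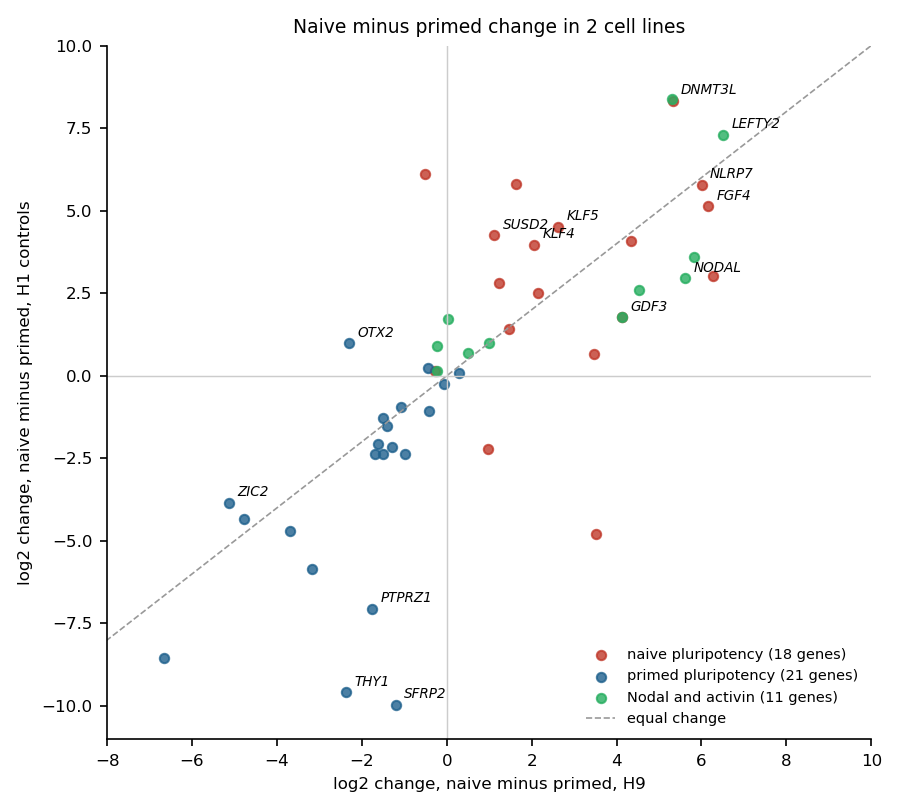
Log2 change, naive minus primed, in H9 (x axis) against H1 nontargeting controls (y axis) for measured genes of the naive pluripotency, primed pluripotency, and Nodal and activin lists (points), leaving out genes with no counts in a group. ZIC2 lies at −5.13 and −3.84 and THY1 at −2.38 and −9.58 in the joint fit.

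Calls of the 3 knockdowns were compared over genes tested in both of a pair, with Fisher's exact test (2-sided), which treats genes as independent. The ZNF8 and ZIC2 knockdowns shared 639 genes higher in both where independent lists would share 267 (Fisher's exact test, adjusted p = 1.78e-124) and 501 lower in both against 221 (adjusted p = 3.85e-83). Fewer than independent lists would share were higher with ZNF8 and lower with ZIC2 (124 against 221, adjusted p = 4.19e-15) or the other way (206 against 267, adjusted p = 1.33e-05). The CARHSP1 and ZNF8 knockdowns shared 284 lower genes against 177 (adjusted p = 3.05e-17) and 213 higher genes against 194 (adjusted p = 0.122). In opposite directions, 305 genes were lower with CARHSP1 and higher with ZNF8 against 179 (adjusted p = 8.92e-23) and 261 the other way against 191 (adjusted p = 7.32e-08). The CARHSP1 and ZIC2 knockdowns shared 276 higher genes against 248 (adjusted p = 0.0481) and 211 lower genes against 189 (adjusted p = 0.0766). In opposite directions, 449 genes were lower with CARHSP1 and higher with ZIC2 against 229 (adjusted p = 1.73e-52) and 304 the other way against 204 (adjusted p = 7.25e-14). The changes of these 2 knockdowns followed GC content in opposite ways. With GC and length trends removed, an alternative chosen after seeing the data, CARHSP1 and ZIC2 shared 361 higher genes against 167 (Fisher's exact test, adjusted p = 1.72e-51) and 229 lower genes against 132 (adjusted p = 1.36e-17). The opposite overlaps then fell to 203 against 129 (adjusted p = 2.17e-11) and 182 against 171 (adjusted p = 0.323). With the same correction CARHSP1 and ZNF8 shared 269 higher genes against 191 (Fisher's exact test, adjusted p = 1.18e-09) and 275 lower genes against 150 (adjusted p = 1.35e-25). Their opposite overlaps stayed above independent lists, with 229 lower with CARHSP1 and higher with ZNF8 against 150 (adjusted p = 1.92e-11) and 245 the other way against 191 (adjusted p = 1.89e-05). In all 3 knockdowns 105 genes were higher, where independent lists would give 30.5, and 84 were lower, against 22.5, of 13698 genes. Genes of mixed direction were not counted over all 3. Since CARHSP1 exceeded independent lists in opposite directions too, these excesses do not by themselves show a shared direction. TAGLN, MYL9, ACTC1, ANXA1 and CDKN1A were higher in all 3, and BNIP3 and LDHA lower, names chosen after their values were seen. The p53 target list, which holds CDKN1A, did not pass in the ZNF8 knockdown (18 genes measured, median log2 −0.02, camera adjusted p = 0.996). No 2 of these knockdowns share control libraries.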

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

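The tests of the naive H9 libraries for primed cells and for depth were chosen only after the result was seen.

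For 5 genes named in both lines, the joint edgeR fit found that the change between naive and primed cells differed between H9 and H1. DNMT3L rose by log2 5.32 in H9 and 8.33 in H1, a difference of −3.01 ± 0.72 (SE; edgeR adjusted p = 0.000843), and LEFTY2 by 6.51 and 7.30, a difference of −0.79 ± 0.16 (edgeR adjusted p = 0.000148). FGF4 rose more in H9, by log2 6.16 against 5.14 (difference 1.02 ± 0.16; edgeR adjusted p = 3.9e-06). ZIC2 fell further in H9, with log2 changes of −5.13 and −3.84 (difference −1.29 ± 0.15; edgeR adjusted p = 1.86e-08). THY1, the surface marker of primed cells, fell far less in H9, with log2 changes of −2.38 and −9.58 (difference 7.20 ± 0.21; edgeR adjusted p = 1.85e-22). Each change keeps its direction in both lines, and all 3 naive libraries lay on the same side of all 3 primed ones in each line for these genes.

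Several genes of the naive list stood high in naive H1 cells and low in naive H9 cells, among them KLF5 at 192 and 13.0 CPM, SUSD2 at 118 and 22.0, KLF4 at 95.5 and 17.9 and IL6R at 93.0 and 7.74, levels set across 2 separate tables. Primed cells left in the naive H9 libraries would have to make up a median of 81.3% of them to give these levels. That share takes naive H1 levels as those of pure naive H9 cells. The 6 genes were picked as low in naive H9 cells, so a high share was built in. Primed list genes kept a median of 35.3% of their primed H9 level (quartiles 19.3% and 47.5%). On that assumption, this argues against primed cells as the whole cause for these genes. Lower depth is argued against as well, since at the H1 level these genes would have had a median of 2885 counts in the naive H9 libraries. The lines themselves, the medium, the time in culture and the doxycycline and nontargeting treatment of H1 alone may each account for the difference, and no test here separates them. Line and treatment differ between every H9 and every H1 library, and any difference in medium or time in culture cannot be told apart from them.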

How the results depend on the processing

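The correction for GC content and gene length and the tests of other splits were chosen only after the results were seen.

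Of the results with a test, 1 that passed turned its direction under an alternative. Mitochondrially encoded genes, called upward in the CARHSP1 knockdown, went downward without passing when GC and length trends were removed (adjusted p = 0.905), and the cause was not tested. Lists that passed neither way are not counted here, and no named gene turned its direction where it passed in either setting. With an adjusted p under 0.01 the counts fell to 1752 for CARHSP1, 2369 for ZNF8 and 2511 for ZIC2. With a change of at least 2-fold they were 240, 579 and 799 for these knockdowns, 2807 for naive against primed H9, 5050 for naive against primed H1 and 3278 for ectoderm. At 0.01 the genes higher in both of 2 knockdowns numbered 112 for CARHSP1 and ZNF8, 157 for CARHSP1 and ZIC2 and 371 for ZNF8 and ZIC2, and those lower in both 154, 96 and 207, as a stricter threshold must lower them. The set of genes highest in primed H9 cells, called in the ZIC2 knockdown, was not called with an estimated correlation (adjusted p = 0.176), nor with the top 50 (0.0979) or the top 500 genes (0.289), and the cause was not tested.

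Leaving out 1 library at a time gave 2045 to 3410 calls for CARHSP1, the lowest without control replicate 1 and the next, 2096, without knockdown replicate 2, 2616 to 3545 for ZNF8, 3042 to 3965 for ZIC2, 7126 to 7900 for H9, 10865 to 11221 for naive against primed H1 and 8736 to 9757 for ectoderm. DESeq2 called 2569, 3224 and 3811 genes in the 3 knockdowns and left 910 genes without an adjusted p in the first. A fit over all H1 groups called 2339, 3165 and 5061. The H9 table holds only its 2 groups, so that alternative was not run there. With GC and length trends removed the knockdowns had 2603, 4113 and 3550 calls, of which 2016, 3533 and 2863 were also called without the correction. Over results and settings, 14 counts of calls moved by over 1.5 times and 214 did not. For named genes 20 calls were lost and 4 gained against 2121 kept on their side, and the 20 concern ZNF8 or CARHSP1 as the target of another knockdown or in naive against primed H1. For lists tested with camera, 73 other calls were lost and 58 gained, while 2515 stayed on their side. With fry, which does not compare a list with other genes, 81 were gained, 1 was lost and 134 stayed.

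The replicate number was not used to pair the libraries, since the labels tie it to nothing shared. Whether same-numbered libraries were handled together is not known. Same-numbered libraries had correlations of their deviations, across genes, of 0.0683 to 0.0864 in the CARHSP1 pair, where each library fitted its own number best, and −0.318 to 0.390 in H9, where 1 of 3 did. In the ZIC2 pair these were 0.00897 to 0.115, and replicates 1 and 2 fitted their own number best. In the ZNF8 pair they were −0.0723 to 0.0654, and no library did so. Fitted as a block, the number gave 3404 calls for CARHSP1, 3631 for ZNF8, 4460 for ZIC2, 7803 for H9, 11073 for naive against primed H1 and 9493 for ectoderm. In the ZIC2 knockdown the block ended the calls of the amnion (adjusted p = 0.078) and primitive endoderm lists (0.0529) and brought NOTCH targets under the threshold (0.0493), and no other list or named gene changed its side.

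For each comparison 1 of the 10 splits of its 6 libraries, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. The real split gave 3152 (CARHSP1), 3702 (ZNF8), 4217 (ZIC2), 8119 (H9), 11289 (naive against primed H1) and 9680 calls (ectoderm), and the highest of the other splits 0 in edgeR in each. At an unadjusted p under 0.05 the highest of the others reached 761, 566, 423, 320, 68 and 148 genes, against 5025, 5326, 5759, 8981, 11574 and 10139.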

Other observations

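The tests of the genes higher in all 3 knockdowns for GC bias and of primed cells as the whole cause of the naive list's fall were chosen only after the result was seen, and so were the genes named in the next 2 paragraphs.

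Of 448 zinc finger genes, 11 (2.46%) were below 0.5 CPM in primed H9 cells and at 5 CPM or more in naive H9 cells, against 35 of 16692 other genes (0.210%). The genes that drew attention to the family are among the 11, so the shares were not tested. Primed H1 cells expressed 6 of the 11 at 5 CPM or more. ZNF667 was at 11.3 CPM in naive H9 and had no counts in primed H9, against 8.66 and 10.1 CPM in naive and primed H1. ZNF595 was at 11.7 CPM and no counts in H9 against 37.3 and 20.8 in H1, and ZNF501 at 11.3 and 0.0342 against 10.1 and 8.17. The change differed between the lines for each of the 3 (edgeR adjusted p = 1.66e-12, 4.94e-14 and 4.04e-13). Close relatives of such genes share sequence, so their counts are uncertain.

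The state change differed between the lines for 8551 of 17140 genes (edgeR, joint fit), of which 4107 had opposite signs. Across genes the changes of H9 and H1 had a Pearson correlation of 0.456 and a Spearman correlation of 0.425, where genes are not independent replicates. MAEL, a germline gene, changed by log2 3.52 in H9 and −4.81 in H1, and OTX2 by −2.31 and 0.98. DPPA3 and DPPA5, both of the naive list, rose by 6.28 and 3.47 in H9 and by 3.03 and 0.66 in H1.

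The 105 genes higher in all 3 knockdowns, where independent lists would give 30.5, and the smaller excess of genes higher with CARHSP1 and ZIC2 (276 against 248) raise the question of a response to the procedure. An excess over independent lists does not by itself show a shared direction. Opposite overlaps exceeded them too for CARHSP1 with ZNF8 (305 against 179 and 261 against 191) and with ZIC2 (449 against 229 and 304 against 204). For ZNF8 with ZIC2 they lay below (124 against 221 and 206 against 267). Genes of mixed direction were not counted over all 3. GC content and gene length are argued against as the cause of the genes higher in all 3. The CARHSP1 and ZIC2 changes followed GC content in opposite ways (Spearman correlation across genes −0.33 and 0.33) and length hardly at all (−0.015 and −0.0015). Opposite trends lower the number of genes that rise in both. With the trends removed 141 genes were higher in all 3 against 22.7, 90 of them among the 105, and 361 were higher with CARHSP1 and ZIC2 against 167. The opposite trends made such a rise likely beforehand, so these counts add little of their own. A raised programme of actin cytoskeleton genes may be part of it. That list was drawn up after TAGLN, MYL9 and several actin genes had been seen, and its other members passed upward in each knockdown (largest camera p = 1.75e-11, and 0.0112 with an estimated correlation). Those other members include ACTB, an actin gene that is itself among the 105. They were thus not held apart from the pattern that prompted the list, and these p-values are no test of it. Of these members 10 of 22, 16 of 21 and 17 of 21 were higher with CARHSP1, ZNF8 and ZIC2, and 1 was lower with ZIC2. Genes of other kinds were higher in all 3 too, such as the tRNA synthetase genes GARS1, YARS1, MARS1 and WARS1, the amino acid transporter genes SLC7A5 and SLC1A5, and PSAT1. These names were chosen after their values were seen and were not tested as a group. The list of the integrated stress and unfolded protein response, which passed with ZNF8 and ZIC2, did not with CARHSP1 (camera adjusted p = 0.105). A response to the procedure and a shared effect of the 3 targets cannot be told apart, since no second control or rescue is among these libraries.

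In the ZNF8 knockdown, genes of the naive, trophoblast, amnion and surface ectoderm lists were lower, although ZNF8 mRNA itself did not pass. All 33 members that fell also did so with GC and length trends removed, which is 100%. In this pair the changes followed GC content and length only weakly (Spearman correlations across genes 0.070 and 0.052), and the correction moved them by a median of 0.029 log2. Trends this weak argue against them as the cause, while the 33 kept calls were likely beforehand and add little. Primed cells as the whole cause are argued against, since by H1 control levels 10 fallen naive genes that are at least 2-fold lower in primed cells would need a median of 53.9% primed cells (quartiles 24.5% and 75.9%), while 106 genes high in primed cells showed a median of 0.46% (quartiles −3.82% and 6.69%). A small rise in their share cannot be told apart from none, since the 200 genes highest in primed H9 cells had a median log2 of 0.032 with members going both ways. Fewer trophoblast-like or amnion-like cells may account for members that fell, but GATA2 of the trophoblast list (log2 −0.22; edgeR adjusted p = 0.339) did not pass and IGFBP3 of the amnion list rose by log2 0.82, and this stays open beside an effect of ZNF8, as neither was tested and which cells express these genes is not known from these libraries.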
